A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

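RNA of Saccharomyces cerevisiae BY4741 with pYES2 or rPLC-pYES2 was labelled with Cy3 and hybridised to 4 single-colour Agilent yeast arrays, 1 per strain and induction time (2 h and 5 h in 2% galactose). The groups and the times come from the labels, and the numbers in the sample titles coincide with the times, so that a term for time is also the replicate block. All 4 arrays lay on 1 slide and were extracted with the same protocol, so slide and scan could not be tested as batches.

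The authors deposited scanner output with spot intensity values, made with Agilent Feature Extraction 10.5.1.1, per the file headers. Agilent Feature Extraction is also the tool named in the submitters' processing notes. The processed intensity was background-subtracted and spatially detrended within each array but not normalized between arrays, per the file headers. The deposited flags, of the unit other, mark spots well above background, saturated spots and outlier spots, per the file headers. The authors also deposited a table of log2 values, whose normalization is not given in the sources used here. Its values were compared with the scanner values: 95.7% to 98.8% of the genes of an array lay within 0.05 log2 units of 1 offset, so its scale is log2 and each array is centred near its 75th percentile, with column medians of −1.39, −1.30, −1.41 and −1.38. No genome build is given in the sources used here, and no coordinates are printed.

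From the scanner files, log2 of the processed intensity minus the array's 75th percentile was used. Control spots (536 per array) were left out. Each gene has 1 probe, in 2 spots (3560 genes) or 3 spots (2696 genes). Spots flagged as outliers were dropped unless all spots of the probe were flagged on that array, and the rest were averaged. A spot kept after this step could still be dim, so genes with agreeing spots were defined as those whose spots, outliers included, lay within 1 log2 unit on each of the 4 arrays. A gene was tested if it was well above background on at least 2 of the 4 arrays (6149 genes, 98.3%). Gene names were taken by locus tag from a RefSeq table (assembly R64), which matched 5756 genes, and the file's own name was kept for the others.

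The fit used lmFit and eBayes of limma 3.58.1 in R 4.3.3 with strain and time as additive terms and Benjamini-Hochberg adjustment. It has 1 residual degree of freedom, which eBayes moderates with a prior of 2.13 degrees of freedom. Differences are rPLC minus vector and 5 h minus 2 h, the values quoted as pairs are those at 2 h and 5 h or in the vector and rPLC strain, in this order, and a positive value means higher in the rPLC strain or at 5 h. SE is the moderated standard error of the mean difference, and n counts pairs of arrays. Named genes were the 12 highest and 12 lowest per comparison by the smaller of the 2 absolute pair differences with the same sign, well above background on both arrays of at least 1 level, first those past an adjusted p of 0.05 and then the others, given as values. Named besides were strain, inducer and pathway genes and, per list described, the 2 members with the largest smaller difference. A gene saturated on all arrays of both levels gets no fold.

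The lists, 23 written in advance and the ribosomal proteins by name, were tested with camera (preset correlation 0.01) and also with an estimated correlation and with fry. Percentiles of list medians are among 10000 random lists matched on mean signal in 20 bins. Besides the lists described with the results, the others are those of phosphoinositide metabolism, galactose use, general stress, heat shock, unfolded protein response, glycolysis, ergosterol synthesis, cell wall integrity, mating pheromone response, Gcn4 amino acid synthesis, oxidative stress, pyrimidine synthesis, and alpha mating type with sporulation, the last as markers of other yeast cell types.

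The method was tested on simulated data made from the mean and spread of the 6149 genes, with 200 genes changed by 1, 2 or 3 log2 units. With a spread of 0.05 log2 units, all changed genes were recovered for both comparisons, at each size, with 11 false calls for rPLC and 9 for time, and 2 lists that were not shifted passed for rPLC. With the spread of the real arrays, 0% were recovered at 1, 2 and 3 log2 units in both comparisons, although the median estimates for rPLC were 1.00, 1.95 and 2.97. A shift of 1 log2 unit put into the histone list was recovered by camera (adjusted p = 0.00203 for rPLC and 5.3e-06 for time). The simulated noise was independent between genes, so this does not test camera on lists whose genes vary together. In the data the estimated correlation was 0.29 for histones and 0.94 for ribosomal proteins. With 1 residual degree of freedom this estimate reflects only how many genes of a list share the sign of the residual.

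Alternatives fixed before the data were examined were normexp background (offset 50), quantile normalization, scaling to the median, no filter or a stricter filter on dim probes, the deposited log2 table, a fit without the other factor, eBayes with trend and robust settings, each array left out, other list tests and a threshold of 0.1. Added after the data were seen were the restriction to agreeing spots, the brightest spot of each probe that was not flagged as an outlier, the restriction of 5 lists to members saturated on no array, and scaling to 5 E1A spike-in probes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.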

Results

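Gene expression was compared between 2 yeast strains that differed in 1 plasmid. Both were BY4741, a laboratory strain of Saccharomyces cerevisiae that is haploid and lacks several amino acid and uracil synthesis genes. The vector strain carried pYES2, a plasmid with a galactose-inducible promoter and a URA3 marker, and the rPLC strain carried the same plasmid with a phospholipase C from rice. Phospholipase C cuts the phosphorylated head group from a phospholipid and leaves diacylglycerol. Each strain was induced with 2% galactose for 2 h and for 5 h, and RNA of each culture was read on 1 single-colour Agilent array. This gave 4 arrays, 2 per strain and 2 per time. The submitters describe the 2 times as 2 biological replicates, but no label says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. In the fit this spread is the difference of the rPLC effect between the 2 times. An rPLC effect that depends on time therefore counts as spread and raises the p-value.

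Each array held 15208 gene spots. Between 96.2% and 97.95% of the spots lay well above background, and the 75th percentile of the signal ranged from 3817 (rPLC, 2 h) to 6247 (vector, 2 h) intensity units. The tests included 6149 genes, 98.3% of those on the array. Spots of the same probe lay more than 1 log2 unit apart for 12.4% of genes on the vector array of 2 h, 5.58% on the vector array of 5 h, 9.26% on the rPLC array of 2 h and 18.8% on the rPLC array of 5 h. In 4295 of the 6149 genes the spots lay within 1 log2 unit of each other on all 4 arrays, and these are called genes with agreeing spots. The number of arrays limits the precision of each value.

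**Figure D1:**
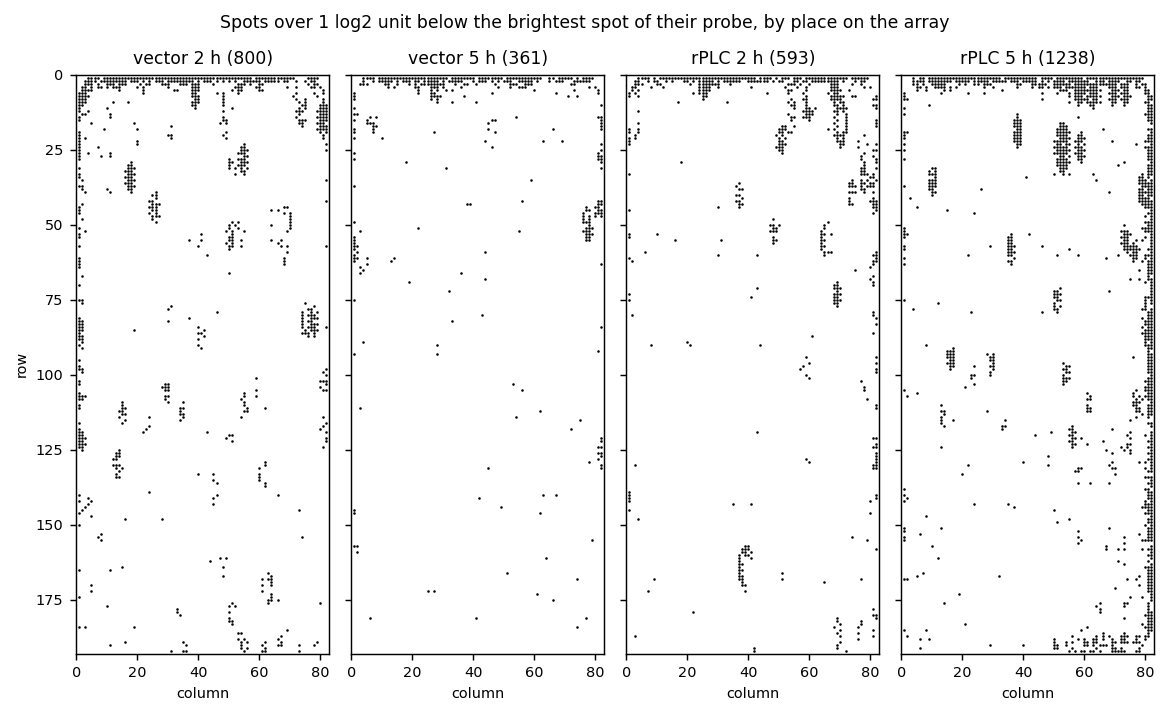
Position (row and column on the array) of each spot that lay over 1 log2 unit below the brightest spot of its probe, with 1 panel per array and 1 point per spot. There were 800 such spots on the vector array of 2 h, 361 on that of 5 h, 593 on the rPLC array of 2 h and 1238 on that of 5 h, and they gathered along the edges and in patches.

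The arrays were first checked against the strain and the inducer. LEU2, HIS3 and MET17, which BY4741 lacks, were not well above background on any of the 4 arrays. The galactose genes GAL1 (galactokinase) and GAL7 (galactose-1-phosphate uridyl transferase) were saturated on all 4 arrays, so the arrays give no difference for them, and GAL10 was saturated on both 5 h arrays. The phospholipid methyltransferase gene OPI3 was also saturated on all 4. URA3 (YEL021W), which BY4741 also lacks, is present on both plasmids, so its signal is read as that of the plasmids. It was 3.04-fold higher with rPLC, at +1.72 log2 units at 2 h and +1.48 at 5 h (mean 1.60 ± 0.22, SE, n = 2 pairs of arrays). It was also 2.00-fold higher at 5 h than at 2 h, by 1.12 in the vector strain and 0.88 in the rPLC strain. The array has no probe for the rice gene, so its own level was not measured. The yeast phospholipase C gene PLC1 stood at +0.10 at 2 h and −0.98 at 5 h with rPLC, but its spots lay 3.25 log2 units apart on 1 array.

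The comparison of the rPLC strain with the vector strain asked which yeast genes respond to the rice enzyme. Of the inositol and phosphate genes named in advance, INO1 differed most. INO1 (YJL153C), the inositol-3-phosphate synthase that makes inositol, was 5.83-fold lower with rPLC, by −2.83 log2 units at 2 h and −2.26 at 5 h (mean −2.54 ± 0.26, SE, n = 2 pairs, unadjusted p = 0.00193). CHO1 (YER026C), the phosphatidylserine synthase, was at −0.74 and −0.55 (unadjusted p = 0.0538). The phosphate transporter gene PHO84 was at −0.61 and −1.70 (unadjusted p = 0.0496), and the acid phosphatase gene PHO5 at −0.46 and −0.42 (unadjusted p = 0.117). No gene passed an adjusted p of 0.05 in limma (0 of 6149, lowest adjusted p = 0.655), while 454 had an unadjusted p under 0.05, 119 higher and 335 lower, where chance gives about 307. In fits without a term for time, this division was 93 higher and 258 lower on all arrays. With 1 array left out, so that 1 strain has a single array and the other gives the spread, it was 69 and 180 without the vector array of 2 h, 269 and 204 without that of 5 h, 48 and 564 without the rPLC array of 2 h, and 67 and 202 without that of 5 h. The lean towards lower turned only without the vector array of 5 h. After quantile normalization the 460 genes with an unadjusted p under 0.05 divided into 193 higher and 267 lower, and after spike-in scaling 1 higher and 1427 lower. Spike-in scaling moved all genes by −1.83 log2 units at 2 h and −0.38 at 5 h. Its division was therefore largely set by the scaling and is no evidence of a lean. When each probe was represented by its brightest spot not flagged as an outlier, a choice made after the data were seen, 30 genes passed, 8 higher and 22 lower, of which 18 had agreeing spots. INO1 was among them (adjusted p = 0.0153), as was the plasmid marker URA3 (adjusted p = 0.0413).

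**Figure D2:**
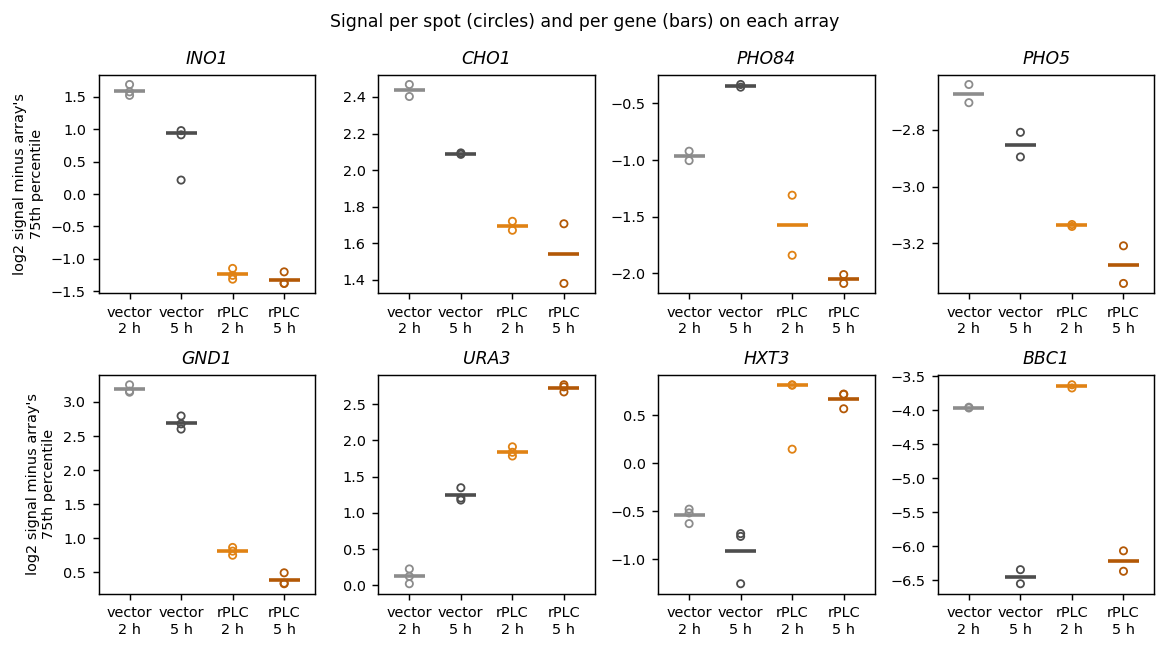
Signal of 8 genes on the 4 arrays, as log2 intensity minus the array's 75th percentile, with 1 circle per spot (outlier-flagged spots drawn too) and a horizontal line at the gene's value. INO1 and GND1 lay lower and URA3 and HXT3 higher on both rPLC arrays, while BBC1 lay lower on both 5 h arrays.

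Among genes with agreeing spots, those lowest in the rPLC strain at both times besides INO1 were of mixed function. GND1 (YHR183W), a 6-phosphogluconate dehydrogenase of the pentose phosphate pathway, was at −2.38 at 2 h and −2.30 at 5 h (mean −2.34 ± 0.21, SE, 5.06-fold lower). On the vector array of 2 h, 1 of its 3 spots was saturated, at 3.25, where the others read 3.14 and 3.16. The sporulation gene SLZ1 was at −3.02 and −2.85, the uncharacterised reading frames YPL044C at −2.86 and −2.84 and YIR042C at −2.46 and −2.32. PUN1, a plasma membrane protein gene, was at −2.02 and −1.68, and the ornithine carbamoyltransferase gene ARG3 at −2.05 and −1.53. The amino acid permease gene AGP1 was at −1.42 and −1.53. On the higher side stood the uncharacterised gene YDL218W at +2.52 and +1.88, the sporulation gene SPS2 at +2.00 and +1.79, and the glucose transporter gene HXT3 at +1.36 and +1.59. The cyclin genes CLN1 (+1.49 and +1.22) and PCL1 (+2.00 and +1.11) and the copper transporter gene CTR1 (+1.67 and +1.21) were also higher. CTR1, PCL1, PUN1, ARG3 and AGP1 are named from the same ranking restricted to agreeing spots, chosen after the data were seen.

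The remaining genes named by the rule fixed in advance had spots that differed by more than 1 log2 unit on at least 1 array, which was so for 7 of the 12 highest and 7 of the 12 lowest. SND1 (YDR186C) gave the lowest value of all, −5.27 at 2 h and −5.61 at 5 h, with 1 of its 2 spots on the rPLC array of 5 h excluded as an outlier at −0.62, where its other spot was at −5.32 and the vector spots at 0.098 to 0.65. HSV2 (−3.21 and −3.84), MCY1 (−5.16 and −2.80), TAE1 (−2.71 and −3.13), RTF1 (−3.43 and −2.66), KRE22 (−3.19 and −2.51) and LYS20 (−2.30 and −2.74) were also of this kind, with spots up to 7.26 log2 units apart in RTF1. With the brightest unflagged spot per probe the mean differences were −5.62 for SND1, −3.04 for MCY1 and −0.97 for LYS20. They were −0.85 for HSV2, −0.55 for KRE22, −0.42 for TAE1 and +0.10 for RTF1. Only the means of SND1 and MCY1 kept most of their size. For MCY1 this came from 2 h, where the brighter spots read −7.56 with rPLC and −2.12 with the vector. At 5 h they read −2.79 and −2.15. For SND1 the rPLC array of 5 h had only 1 unflagged spot, so this choice could not change its value there. The higher genes of this kind were PRM2 (+1.91 and +1.92), PUL3 (+1.84 and +1.65), NCA3 (+1.63 and +1.52), FMP48 (+3.07 and +1.47), TPO1 (+1.63 and +1.33), FRE7 (+3.04 and +1.29) and SLS1 (+1.34 and +1.28), with means from +1.08 (SLS1) to +2.35 (FRE7) by the brightest spot.

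Gene lists fixed before the data were examined were then tested as sets with camera, which compares a list with all other genes at a preset correlation of 0.01. Of 24 lists, 8 passed an adjusted p of 0.05 for rPLC, 2 towards higher and 6 towards lower levels. With the correlation estimated from the 4 arrays none passed (adjusted p = 0.929 to 0.986), and with fry none passed either (lowest adjusted p = 0.0661). Both of these tests rest on the 1 residual degree of freedom of the fit, so they could hardly pass any list. The adjusted p values with an estimated correlation given below therefore do not show whether correlation between genes accounts for a shift. The estimated correlation was 0.94 for ribosomal proteins and −0.02 for TCA cycle and respiratory chain genes. With 1 residual degree of freedom it reflects only how many genes of a list share the sign of the residual. It therefore does not measure how far the genes of a list vary together.

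Methionine and sulphur genes were lower as a set, with a median of −0.52 log2 units, and 17 of 22 were lower and 1 higher at both times (camera adjusted p = 6.14e-05, adjusted p = 0.929 with an estimated correlation). None of them passed over all genes and 3 did when adjusted over the list alone. These were MET32, a transcriptional regulator of sulphur genes, at −2.22 and −2.30, MMP1, an S-methylmethionine permease, at −1.72 and −1.79, and CYS3, cystathionine gamma-lyase, at −1.56 and −1.33. The spots agreed in CYS3, but lay 5.32 log2 units apart in MET32 and 2.60 in MMP1 on 1 array.

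Of the 17 phospholipid genes with an inositol-sensitive promoter element (UASINO), 12 were lower and 1 higher at both times, with a median of −0.46 (camera adjusted p = 0.00501, adjusted p = 0.929 with an estimated correlation). No member passed over all genes and 1, INO1, passed when adjusted over the list alone. The choline transporter gene HNM1 was at −1.01 and −1.79 with disagreeing spots. The list's median was −0.62 at 2 h, below all 10000 random lists matched on signal, and −0.26 at 5 h, at percentile 8.36. Of the 20 phosphate regulon genes, 14 were lower and 3 higher at both times (median −0.35, camera adjusted p = 0.0119, adjusted p = 0.929 with an estimated correlation). SPL2, a regulator of phosphate transport, was at −1.75 and −1.80 with disagreeing spots, and the phosphatase gene PHM8 at −0.88 and −1.37. In this list 0 genes passed over all genes and 0 when adjusted over the list alone.

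The iron regulon had 13 of 20 members lower and 1 higher at both times (median −0.44, camera adjusted p = 0.00501, adjusted p = 0.929 with an estimated correlation), among them the ferric reductase gene FRE5 at −1.32 and −1.39 and the siderophore transporter gene SIT1 at −1.01 and −1.17. The spots of both differed by more than 1 log2 unit on an array, and 10 of the 20 members had agreeing spots. Under spike-in scaling, chosen after the data were seen, the list's adjusted p was 0.136. Histone genes were lower at both times in 8 of 10 cases and higher in 0 (median −0.46, camera adjusted p = 0.0119, adjusted p = 0.957 with an estimated correlation). HTB2 was at −0.80 and −0.94, and HHF2 at −3.28 and −1.40 with disagreeing spots. Calcineurin-Crz1 targets are genes switched on by calcium signalling, and their list also holds genes of the pathway itself, such as CRZ1. Its members were lower at both times in 11 of 17 cases and higher in 2 (median −0.24, camera adjusted p = 0.0487, adjusted p = 0.939 with an estimated correlation). PUN1 stood at −2.02 and −1.68 and RCN2 at −0.70 and −0.74, and the list's adjusted p was 0.0643 with median scaling and 0.181 with spike-in scaling. In each of these 3 lists 0 genes passed over all genes and 0 when adjusted over the list alone.

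The lists that were higher with rPLC were those of the TCA cycle with the respiratory chain and of ribosomal proteins. Of 44 TCA cycle and respiratory chain genes, 21 were higher and 4 lower at both times (median +0.28, camera adjusted p = 4.99e-05, adjusted p = 0.929 with an estimated correlation). The median was 0.35 at 2 h and 0.39 at 5 h. On the vector array of 2 h, 8 of the 44 were saturated, and over the 36 saturated on no array, a restriction chosen after the data were seen, the medians were 0.33 and 0.42. The members with the largest differences of 1 sign were LSC2 (−1.13 and −1.69) and SDH1 (−1.20 and −1.57), which were lower and had disagreeing spots. SDH1 was saturated on the vector array of 2 h, where its spots read 4.09 and 3.43. On the rPLC array of 2 h the same spots read 2.14 and 2.97, so its −1.20 is not exact and may err either way. LSC2 stood at +0.23 with the brightest spot per probe. No member passed over all genes or when adjusted over the list alone (0 of 44). Ribosomal protein genes had a median of +0.38 over both times (camera adjusted p = 4.99e-05, adjusted p = 0.986 with an estimated correlation), but it was 1.09 at 2 h and −0.36 at 5 h, and only 23 of the 137 genes were higher and 7 lower at both times. Without either 2 h array the list's median lay −0.28 from that of all genes. RPL41B was at −1.13 and −1.39 and RPL35A at −1.08 and −0.81, both with disagreeing spots. No ribosomal protein gene passed over all genes or when adjusted over the list alone (0 of 137).

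The rPLC effects at 2 h and at 5 h, which share no array, correlated across the 6149 genes with Pearson r = 0.195 and Spearman rho = 0.209. Genes are not independent replicates, so no p is given. Across the 4295 genes with agreeing spots Pearson r was 0.337 and Spearman rho 0.287. Signs agreed upwards in 1532 genes (24.9%) and downwards in 2026 (32.9%). A difference of at least 2-fold in the same direction at both times was found in 26 higher and 108 lower genes, of which 16 and 34 had agreeing spots. The difference of the effects between the times had no residual degrees of freedom and was not tested.

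**Figure D3:**
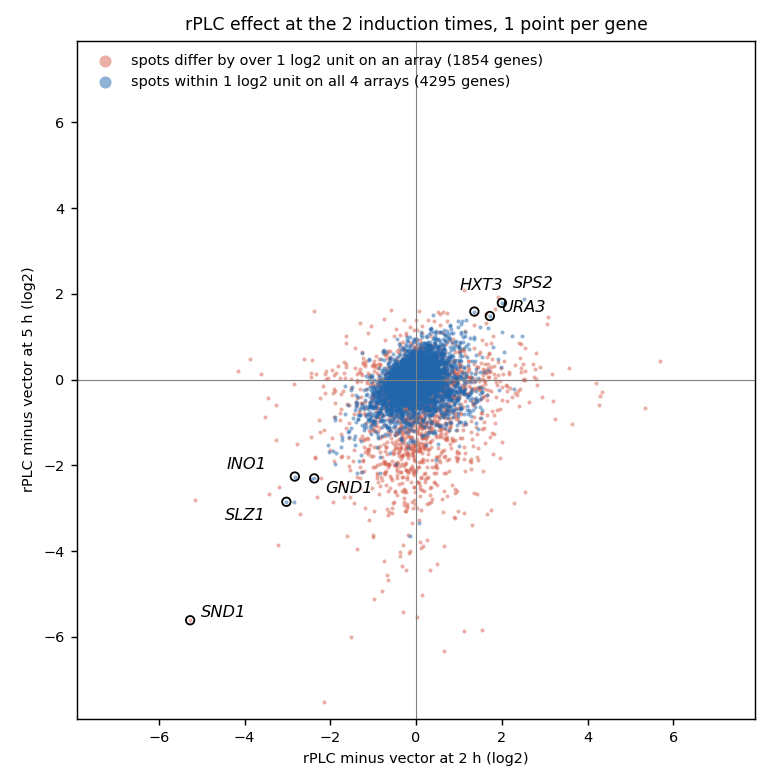
The difference between the rPLC and vector strains (log2) at 2 h (x axis) and at 5 h (y axis), with 1 point per gene, blue for the 4295 genes with agreeing spots and red for the other 1854. INO1, GND1, SLZ1 and SND1 lie low on both axes and URA3, SPS2 and HXT3 high, and most points far from the centre on 1 axis alone are red.

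The second comparison, of 5 h with 2 h of galactose, asked how expression moved during induction in both strains. BBC1 (YJL020C), which takes part in assembling actin patches, was 5.77-fold lower at 5 h, by −2.49 log2 units in the vector strain and −2.57 in the rPLC strain (mean −2.53 ± 0.21, SE, n = 2 pairs, unadjusted p = 0.000963). Higher were 2 genes of sterol synthesis, a list that did not pass as a whole (camera adjusted p = 0.0962), with ERG5 (YMR015C), a sterol desaturase, at +1.96 and +1.35 (3.15-fold) and ERG25, a methyl sterol oxidase, at +1.66 and +1.13. Malate synthase MLS1 of the glyoxylate cycle was at least 3.02-fold lower, by −1.87 and −1.32, since it was saturated on the vector array of 2 h. No gene passed an adjusted p of 0.05 in limma (0 of 6149, lowest adjusted p = 0.582), and 486 had an unadjusted p under 0.05, 146 higher and 340 lower, where chance gives about 307. In fits without a term for strain it was 140 higher and 296 lower on all arrays. With 1 array left out, so that 1 time has a single array, it was 116 and 122 without the vector array of 2 h, 38 and 565 without that of 5 h, 287 and 181 without the rPLC array of 2 h, and 147 and 173 without that of 5 h. After quantile normalization the division was 218 higher and 274 lower, and after spike-in scaling 9 higher and 586 lower. The latter was largely set by the scaling, which moved all genes by −1.45 log2 units in the vector strain. With the brightest spot per probe, chosen after the data were seen, 1 gene passed, BBC1 (adjusted p = 0.0478).

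Among genes with agreeing spots, the transporter gene AZR1 was at −3.10 in the vector strain and −1.99 in the rPLC strain, YAR062W at −1.61 and −2.09, and the flocculin gene FLO9 at −1.57 and −2.01. On the vector array of 5 h the AZR1 spots read −9.74 and −8.85. The lowest gene value well above background there was −8.87, so the −3.10 is not exact. CSN9 was higher, at +1.21 and +1.28. Of the genes named by the rule fixed in advance, 10 of the 12 highest and 8 of the 12 lowest had disagreeing spots. The lower ones of these were SDH1 (−1.91 and −2.28), YBL100C (−1.65 and −2.49), TRK2 (−2.36 and −1.59), YPP1 (−1.57 and −2.78), CHA1 (−1.55 and −1.69), FIT1 (−1.50 and −1.47), COX19 (−1.45 and −1.56) and TIR1 (−1.90 and −2.75), the last of them saturated on both 2 h arrays and SDH1 on the vector array of 2 h. The higher ones were CCC1 (+2.70 and +2.26), GLG1 (+3.87 and +2.08), GTR1 (+1.91 and +2.58), IMD3 (+1.59 and +1.81), DPH6 (+1.55 and +1.44), SNU13 (+3.66 and +1.28), OGG1 (+1.25 and +1.61), ESF2 (+3.04 and +1.20), TMA23 (+2.71 and +1.20) and RPL12A (+1.58 and +1.14). With the brightest spot per probe the means of these higher genes were smaller, from +1.19 for TMA23 and +1.09 for OGG1 down to +0.18 for ESF2, +0.01 for CCC1 and −0.46 for GLG1, and those of the lower genes lay between −1.75 (YPP1) and −0.56 (TRK2).

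Of the 24 lists, 5 passed for time with camera at the preset correlation, 2 towards higher and 3 towards lower levels at 5 h, and none passed with an estimated correlation (adjusted p = 0.909 to 0.988) or with fry (lowest adjusted p = 0.619). As for rPLC, the tests with an estimated correlation and with fry rested on 1 residual degree of freedom and could hardly pass any list. TCA cycle and respiratory chain genes were lower, 38 of 44 in both strains and 0 higher (median −0.56, camera adjusted p = 1.21e-10, adjusted p = 0.909 with an estimated correlation). SDH1, a subunit of succinate dehydrogenase, was at −1.91 and −2.28 and ATP1, a subunit of ATP synthase, at −1.19 and −2.75, both with disagreeing spots and each saturated on 1 array, while over the 28 members with agreeing spots the median was −0.51. Genes of gluconeogenesis, the glyoxylate cycle and glucose repression were lower in both strains in 14 of 22 cases and higher in 0 (median −0.55, camera adjusted p = 0.000446, adjusted p = 0.909 with an estimated correlation). MLS1 was at −1.87 and −1.32 and isocitrate lyase ICL1 at −0.80 and −0.87, each saturated on 1 array. On the vector array of 2 h, 13 of these 22 genes and 8 of the 44 of the TCA cycle and respiratory chain were saturated. Over the members saturated on no array, a restriction chosen after the data were seen, the median was −0.56 for the 9 genes of gluconeogenesis, −0.82 in the vector strain and −0.30 in the rPLC strain, and −0.54 for the 36 of the TCA cycle. Hexose transporter genes were lower in both strains in 10 of 17 cases and higher in 1 (median −0.34, camera adjusted p = 0.0293, adjusted p = 0.909 with an estimated correlation), with HXT16 at −1.44 and −0.79 and HXT15 at −0.67 and −1.35, both with disagreeing spots. This list's adjusted p was 0.128 with normexp background, 0.142 with quantile normalization, 0.0880 with no replicate block and, in alternatives chosen after the data were seen, 0.173 with agreeing spots and 0.0807 with spike-in scaling. In these 3 lists 0 genes passed over all genes and 0 when adjusted over the list alone.

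Ribosomal protein and ribosome biogenesis genes were higher at 5 h in the fit over both strains, with medians of 0.53 and 0.65 (camera adjusted p = 9.25e-09 and 3.67e-05, adjusted p = 0.909 for both with an estimated correlation). In the vector strain the medians were 1.23 and 1.31, and in the rPLC strain −0.28 and −0.05. The direction therefore came from the vector strain, and without either vector array the medians lay −0.25 and −0.01 from that of all genes. On the vector array of 2 h the spike-in RNA probes also lay lower against the yeast genes than on the other 3. Higher in both strains were 36 of 137 ribosomal protein genes and 11 of 28 ribosome biogenesis genes, and lower in both were 0 and 0. RPL12A was at +1.58 and +1.14, RPL35A at +0.89 and +1.17, NUG1 at +1.34 and +1.09 and IMP4 at +0.91 and +1.13, all with disagreeing spots. None passed over all genes or when adjusted over the list alone (0 and 0).

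**Figure D4:**
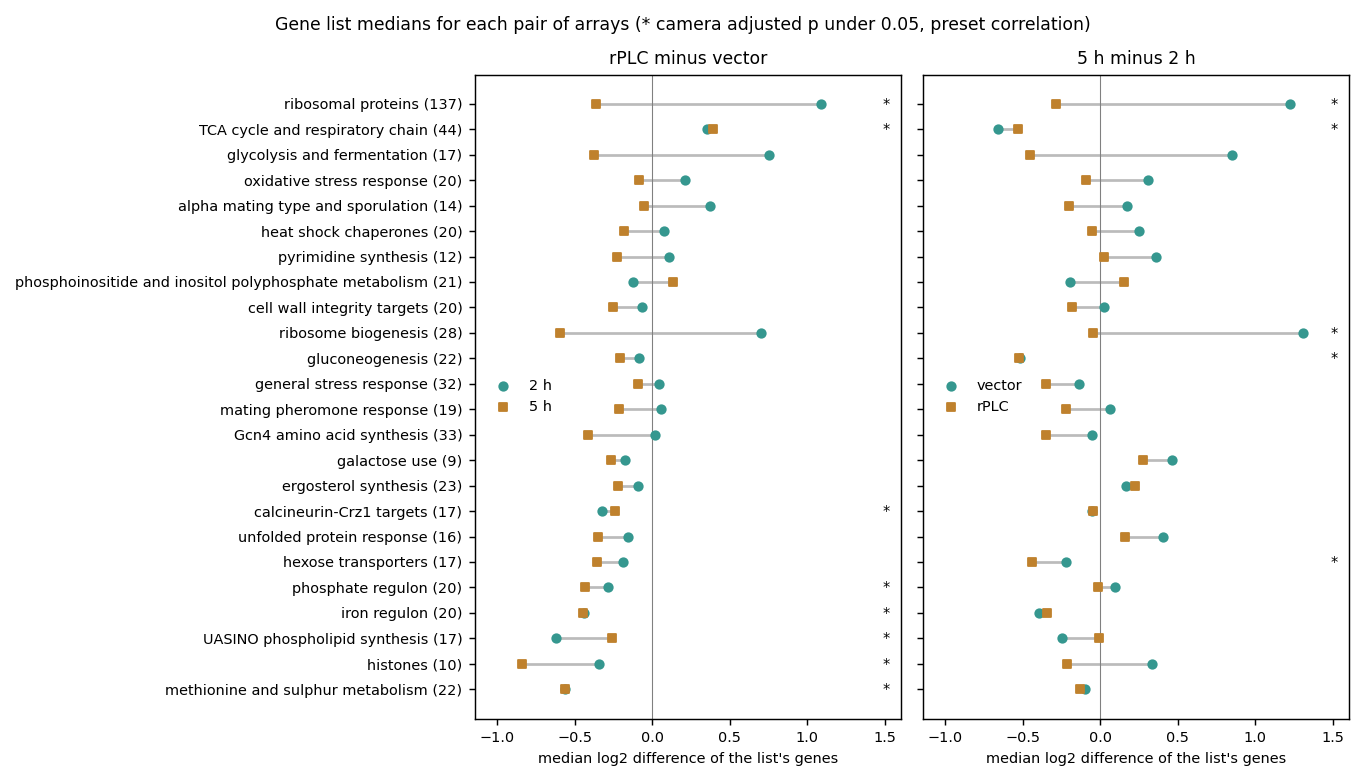
Median log2 difference of the genes of each of 24 lists, with the number of measured genes in brackets, for rPLC minus vector at 2 h (circles) and 5 h (squares) on the left and for 5 h minus 2 h in the vector strain (circles) and the rPLC strain (squares) on the right. Ribosomal proteins (1.09 and −0.36 on the left) lie on both sides of 0, while methionine and sulphur genes (median −0.52) lie below 0 at both times, and an asterisk marks lists past the preset-correlation camera test.

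The time effects of the 2 strains, which also share no array, correlated across 6149 genes with Pearson r = 0.194 and Spearman rho = 0.289, and across the 4295 genes with agreeing spots with r = 0.403 and rho = 0.409. They had the same sign upwards in 1793 genes and downwards in 1989. At least 2-fold in the same direction in both strains were 19 higher and 74 lower genes, of which 4 and 36 had agreeing spots.

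**Figure D5:**
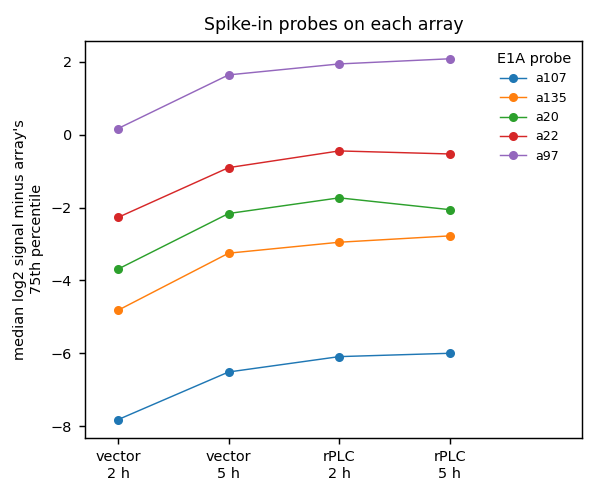
Median signal of each of 5 E1A spike-in probes on the 4 arrays, as log2 intensity minus the 75th percentile of the array's gene spots, with 1 line per probe. Their mean was −3.69 on the vector array of 2 h, −2.24 on that of 5 h and −1.86 on both rPLC arrays.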

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

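All tests in this part were chosen after the results were seen. The median rPLC effect had opposite signs at the 2 times in 11 of 24 gene lists, and in 3 of them it lay outside the middle 95% of random lists at both times. From 2 h to 5 h the median effect of ribosomal proteins changed by −1.45 log2 units (from 1.09 to −0.36), that of ribosome biogenesis by −1.30 (from 0.70 to −0.60) and that of glycolysis and fermentation by −1.13 (from 0.75 to −0.38). For glycolysis 10 of 17 genes were saturated on at least 1 array, and over the other 7 the median went from 0.25 to −0.60, so its size at 2 h rests in part on saturated values. The difference between the times rests on 1 array per strain and time and was not tested.

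Ribosomal protein genes lay −1.03 log2 units (median) below the mean of the other 3 arrays on the vector array of 2 h, and 0.65 above it on that of 5 h. For ribosome biogenesis these values were −0.85 and 0.93, and for the 7 glycolysis genes saturated on no array −0.70 and 0.94. The levels therefore do not place the pattern on the array of 2 h alone.

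The next values are levels of ribosomal proteins on the vector array of 2 h minus those predicted additively from the other 3 arrays, a contrast that has the same size whichever array is out of place. The bootstrap intervals resample the genes of a list and not the arrays, so they show only the spread between genes. Compression of bright spots is argued against, because the median was −1.28 after quantile normalization (bootstrap 95% interval −1.43 to −1.16, 137 genes), against −1.43 before. Failed spots are argued against by the 90 genes with agreeing spots, where it was −1.41. For 24 unsaturated general stress genes the contrast was 0.0054 (interval −0.17 to 0.44), but they lay 0.28 above the mean of the other 3 arrays (interval 0.024 to 0.40). They also lay 0.22 above it on the rPLC array of 2 h (interval −0.11 to 0.47), where ribosomal proteins lay 0.39 higher, so a rise particular to the vector culture was not shown, and a weak one stays open. A strain difference that depends on time, another growth state of a culture and the preparation of an RNA sample also stay open and were not tested.

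Spike-in probes, which the comparisons do not use, set the vector array of 2 h apart. The 5 E1A probes lay −1.70 log2 units below the mean of the other 3 arrays, relative to the 75th percentile of the genes.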

How the results depend on the processing

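The restriction to agreeing spots, the brightest spot and spike-in scaling were chosen after the data were seen. Both counts of changed genes stayed at 0 under each alternative planned in advance. With the brightest spot they were 30 (rPLC) and 1 (time), and with spike-in scaling 212 and 23. That scaling moved all genes by −1.83 log2 units for rPLC at 2 h, −0.38 at 5 h and −1.45 for time in the vector strain, so single genes are compared relative to the shift. With each array left out, in fits without the block, the counts were 0 to 0. With no replicate block the counts were 0 and 0 genes, and 8 and 4 lists in place of 8 and 5. The numbers in the titles coincide with the times, so this fit leaves out a condition. At an adjusted p under 0.1 the time lists numbered 10, by the looser threshold. Camera with an estimated correlation gave 0 and 0 lists and fry 0 and 0. Both rest on 1 residual degree of freedom, so that they passed no list was nearly given in advance. The correlation of the 2 rPLC effects was 0.337 with agreeing spots and 0.295 with the brightest spot, and that of the time effects 0.403, 0.316 and, with normexp background, 0.168. The cause was not tested.

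Single genes gave 1919 comparisons with alternatives, of which 23 moved past the threshold (all with the brightest spot) and 7 changed sign. For spike-in scaling only the sign was scored, so genes that passed there are not among the 23. The 1919 include 528 values with an array left out, for which neither was scored. With an array left out, a gene's value is the difference of the other pair, so each value is counted for both arrays of a pair. Of these 528 values, 6 more, all of PLC1 and PHO84, had the other sign. Most named genes were chosen for the same sign in both pairs, so their sign could not change here. With the brightest spot GLG1 (time) stood at −0.46, LSC2 (rPLC) at 0.23, RTF1 (rPLC) at 0.10, PLC1 at 0.14 for rPLC and 0.14 for time, and PHO84 (time) at −0.056, or −0.018 with normexp background. Lists gave 768 comparisons, of which 34 fell short of the threshold, 26 of them with an estimated correlation or fry, 11 newly passed and 31 changed sign. With an array left out, 42 of 192 list values had the other sign, of which the 6 of called lists are among the 31. Here too each value is counted for both arrays of a pair.

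List medians, relative to all genes, reversed as follows. Called lists did so only when an array was left out: ribosomal proteins from −0.28 (without either 2 h array) to 1.11 for rPLC and from −0.25 (without either vector array) to 1.22 for time, and ribosome biogenesis from −0.011 (without either vector array) to 1.31 for time. The others passed in neither case. With the brightest spot, for rPLC: general stress 0.14, hexose transporters 0.016, phosphoinositide metabolism 0.066, pyrimidine synthesis 0.068, ribosome biogenesis 0.0061; for time: alpha mating type −0.0050, pheromone response 0.018, phosphate regulon −0.026. With agreeing spots, for rPLC: Gcn4 targets 0.011, general stress 0.040, heat shock −0.081, phosphoinositide metabolism 0.054; for time: pheromone response 0.051, phosphate regulon −0.031. With quantile normalization, for rPLC: glycolysis −0.057, heat shock −0.094, oxidative stress −0.0074, ribosome biogenesis 0.023; for time: calcineurin targets 0.010, cell wall integrity 0.0013. With the deposited table, for rPLC: heat shock −0.11, pyrimidine synthesis 0.045. With normexp background, ribosome biogenesis 0.0019 (rPLC) and phosphoinositide metabolism 0.0031 (time), which was 0.0015 with no filter. The cause was not tested. The probe with the highest signal per gene was not run, since each gene has 1 probe, nor was the slide as a block, since there is 1 slide. Signal over background limits little, since 98.3% of genes were bright enough to test.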

Other observations

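Other lists held single genes with differences in both pairs, though none of these lists passed for rPLC. PIS1, the phosphatidylinositol synthase, was at −0.80 at 2 h and −1.31 at 5 h, and VPS34, a phosphatidylinositol 3-kinase, at +0.49 and +0.51, while the phosphoinositide list had a median of −0.07 (camera adjusted p = 0.869). The hexokinase gene HXK2 was at −1.37 and −2.17 and PDC5, a pyruvate decarboxylase, at −1.01 and −0.60 (glycolysis, adjusted p = 0.633). The catalase gene CTT1 was at +1.34 and +0.95 and RTN2 at +1.15 and +1.14, the latter with disagreeing spots (general stress, median −0.12, adjusted p = 0.812). SIL1, an exchange factor of the endoplasmic reticulum chaperone, was at −0.69 and −0.73 (unfolded protein response, median −0.26, adjusted p = 0.0808), and ERG6 at −1.61 and −3.63 with disagreeing spots (ergosterol synthesis, adjusted p = 0.152). For the galactose list the median was −0.17 (adjusted p = 0.497), with PGM2 at −0.71 and −0.32. On the vector array of 2 h 4 of its 9 genes were saturated. The remaining adjusted p values for rPLC were 0.152 for Gcn4 targets, 0.214 for alpha mating type and sporulation, 0.811 for pyrimidine synthesis, 0.811 for hexose transporters, 0.812 for pheromone response, 0.815 for oxidative stress, 0.869 for heat shock, 0.869 for gluconeogenesis, 0.925 for cell wall integrity and 0.925 for ribosome biogenesis. FRE1, a copper and iron reductase gene noticed after its values were seen, stood at +0.62 and +0.61.

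Median, mean and camera direction differed in sign for general stress (median −0.12, camera up), phosphoinositide metabolism (median −0.07, camera up) and oxidative stress (median 0.08, mean −0.05, camera up) by rPLC, and for cell wall integrity (median −0.04, mean 0.0018, camera up) by time.

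For time, the iron regulon did not pass as a list (median −0.22, camera adjusted p = 0.0962), but 4 of its 20 genes passed when adjusted over the list alone and 0 over all genes. These were FIT1 (−1.50 in the vector strain and −1.47 in the rPLC strain), FIT2 (−1.35 and −1.33) and FIT3 (−1.50 and −1.27), mannoproteins that hold siderophores in the cell wall, and FRE5 (−1.24 and −1.31), with disagreeing spots in FIT1 and FRE5. Sterol synthesis had a median of 0.10 (adjusted p = 0.0962), glycolysis 0.17 (adjusted p = 0.0962) with ENO2 at +1.66 and +0.76, general stress −0.16 (adjusted p = 0.0962) with XBP1 at −1.36 and −0.71, and galactose use 0.40 (adjusted p = 0.0865) with GAL80 at +0.40 and +0.41 and disagreeing spots. Of the 9 galactose genes 4 were saturated on the vector array of 2 h and 2 on all 4 arrays, so this list's shift rests in part on saturated values. KAR2, the endoplasmic reticulum chaperone, was at +1.04 and +0.75. The other lists had an adjusted p between 0.165 (pyrimidine synthesis) and 0.970 (cell wall integrity).

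The tests of the next 2 patterns were chosen after the results were seen. Of the 134 genes at least 2-fold apart in the same direction at both times by rPLC, 62.7% had disagreeing spots, against 30.2% of all genes tested, given without a p since neighbouring genes are not independent. Failed spots may therefore account for part of these differences. With the brightest unflagged spot 17 of the 84 with disagreeing spots stayed at least 2-fold apart at both times. Dim spots had dim neighbours, since 34.2% to 47.1% of the spots within a window of 5 rows and 5 columns around them were dim, against 2.37% to 8.14% of all spots. The 50 genes with agreeing spots stay open to other explanations.

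Of the 17 UASINO genes, INO1 among them, 12 were lower with rPLC at both times. The list passed with camera at the preset correlation but not with fry (adjusted p = 0.220). The latter test rests on 1 residual degree of freedom and could hardly pass any list. Failed spots are argued against, because the 11 members with agreeing spots had a median of −0.44 (bootstrap 95% interval over genes −0.59 to −0.22), and the spots of INO1 differed by at most 0.76 log2 units. A candidate explanation is repression of the whole list, which inositol is known to bring about. Without INO1 the median of the other 16 genes was −0.61 at 2 h, at percentile 0 of random lists, and −0.24 at 5 h, at percentile 11.87, so at 5 h a shift of the list cannot be told apart from that of random lists. Inositol was not measured, and other routes from the enzyme to INO1 were not tested.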
